A study of Mus musculus with 9 samples.

How the data were processed

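Total RNA of FACS-sorted LSK cells was made into stranded libraries after ribosomal RNA removal, per the labels' protocols. Per the submitters' processing notes, STAR, HTSeq 0.5.3p3 and DESeq2 were used with the mouse build mm10 (GRCm38); the versions of STAR and DESeq2, the annotation and whether reads were counted by strand are not given in the sources used here, so overlapping genes on opposite strands are uncertain. The authors deposited a table of raw counts per Ensembl gene, with 39179 gene rows and 5 rows that name no gene. The second table, whose unit is a scaled signal, equals the deposited counts divided by 1 factor per library, to a relative tolerance of 5.11e-15. These factors equal DESeq2 size factors computed over all rows, including the 5 that name no gene, and this table entered no test.

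The rows that name no gene held 40.5% to 47.3% of all counted reads per library and were left out of library sizes and tests. Reads that did not align uniquely made up 21.6% to 28.3%, so near-identical gene copies are undercounted. Gene totals ranged from 47792306 to 58405879 counts. Symbols and coordinates came from the GENCODE annotation of GRCm38, which matched 37607 of the 39179 identifiers.

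Groups and library numbers were taken from the sample titles. The numbers differ between groups and pair no libraries, and the labels name no batch. Libraries of 1 group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 13.4, so each counted as 1 replicate.

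Genes were kept with filterByExpr by group (18576 genes) and scaled by TMM. The quasi-likelihood test of edgeR 4.0.16 was fitted to all 9 libraries with 1 mean per group, and p-values were adjusted by Benjamini-Hochberg at 0.05, two-sided. Standard errors are the log2 fold change divided by the square root of its F statistic. Dnmt3a, the targeted gene, was adjusted over its 3 comparisons. Values in CPM use the TMM-scaled library sizes. The other tools were limma 3.58.1, DESeq2 1.42.0 and R 4.3.3.

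The 28 gene lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The sex-linked marker genes served as a check, and the other 27 lists were tested with camera on voom values (inter-gene correlation 0.01, at least 5 measured members), again with an estimated correlation, and with fry; 6 list symbols had no match. List medians come from the voom fit, and the signs of members from edgeR. Camera compares a list with the other genes, whereas fry asks whether its members move one way. Named genes were, among those past the threshold with a mean of at least 1 CPM and not sex-linked or known by a clone name, the 12 with the largest change in each direction; where fewer than 10 passed, the 10 such genes with the lowest unadjusted p were given as values. Dnmt3a and up to 4 members of each list with the lowest p were added. Some genes and libraries that these rules would name are not reported here.

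The alternatives were RLE and upper-quartile scaling, DESeq2, limma-voom with quality weights, no filter and a filter of 1 CPM in 4 libraries, only the groups compared, other thresholds, removal of Y-linked genes and Xist or of histone, mitochondrial and small RNA genes, a covariate for Y-linked transcripts, and each library left out in turn. The coding of this covariate by Y-linked transcripts alone was chosen after the levels of Xist and the Y-linked genes were seen, because 1 library held neither. Of the libraries, 5 held Y-linked transcripts and 4 did not, and each group had both kinds. Further alternatives chosen after the data were seen are named in the closing section.

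The edgeR step was tested on simulated data drawn from the means, spread and library sizes of the real libraries, with 200 genes changed. In the simulation of mutant against wild type, run on 18252 genes, 14.9% of genes changed 1.5-fold were called, 50.7% of those changed 2-fold and 95.5% of those changed 4-fold. For Cre-negative against wild type (18223 genes) the shares were 8.96%, 52.2% and 87.9%, and for mutant against Cre-negative (18248 genes) 8.96%, 49.3% and 90.9%. Each gene was drawn independently, and the Benjamini-Hochberg threshold eases as more genes change. The shares therefore hold for 200 changed genes and may be too high where fewer genes change.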

Results

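RNA was measured in LSK cells, the lineage-negative, Sca1-positive and cKit-positive fraction of mouse bone marrow that holds stem cells and early progenitors. The cells came from animals aged 6 months that had received 5 injections of poly(I:C), a double-stranded RNA that switches on the Mx1-Cre recombinase through interferon. Wild-type animals carrying Mx1-Cre gave 3 libraries, animals with Mx1-Cre and a conditional mutant Dnmt3a allele gave 4, and animals with the conditional allele but no Cre gave 2. The design text gives this last group the genotype Dnmt3a+/-, and its difference from wild type therefore joins the Dnmt3a allele with the absence of Cre. Counts assigned to genes ranged from 47792306 in cre_negative_780 to 58405879 in cre_negative_819; libraries are named by group and by the number in the sample title.

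Dnmt3a, the de novo DNA methyltransferase targeted in this model (ENSMUSG00000020661, chromosome 12, 3806007 to 3914443 of GRCm38, protein-coding), stood at 159 ± 12.9 CPM (SD, n = 3) in wild type and 160 ± 7.69 (SD, n = 4) in mutant libraries. The Cre-negative libraries held 118 and 93.5 CPM, both below each of the other 7 libraries. The Cre-negative level fell by 0.59 on the log2 scale against wild type (SE 0.13), with an adjusted p of 0.0011 over the 3 comparisons of this gene in edgeR's quasi-likelihood test. It was also below the mutant level, by a mutant-minus-Cre-negative log2 difference of 0.60 (SE 0.12, adjusted p = 0.0011 in the same edgeR test). Mutant and wild type differed by 0.01 (95% interval -0.22 to 0.24), with an adjusted p of 0.93 in edgeR. Adjusted over all genes tested, the edgeR p was 0.594 for Cre-negative against wild type and 0.8005 for mutant against Cre-negative. Gene-level counts do not separate the mutant from the wild-type transcript.

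**Figure D1:**
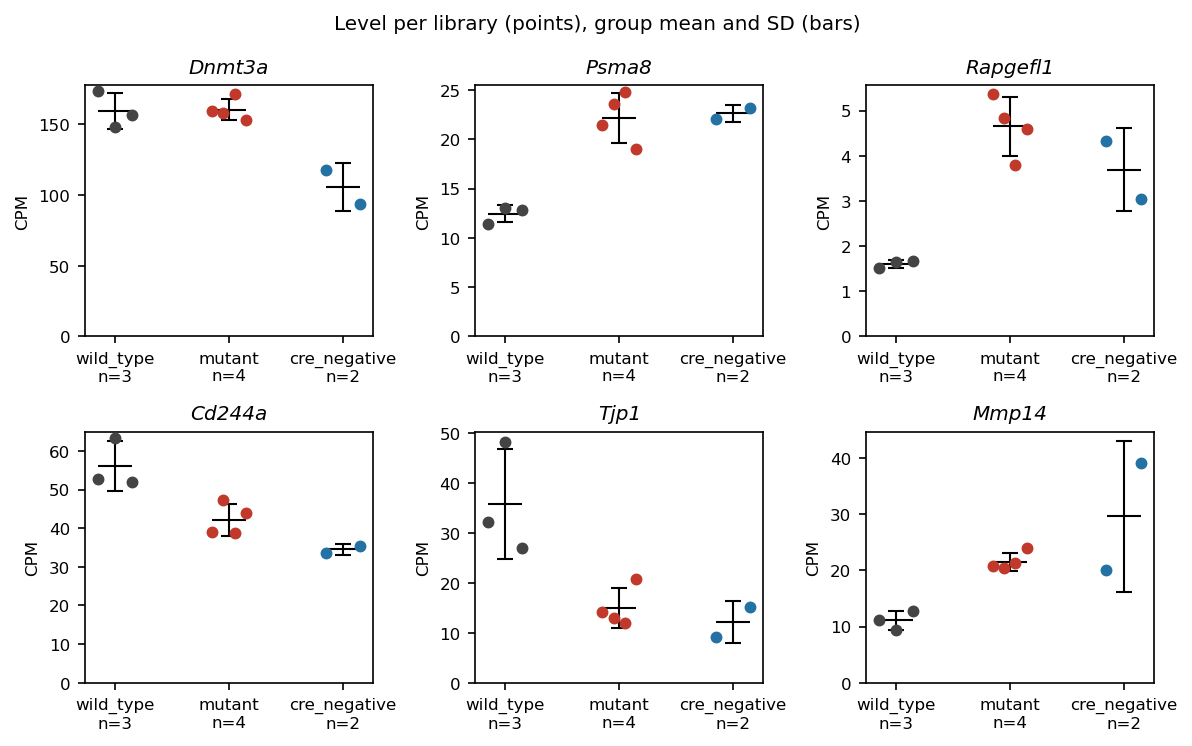
CPM (vertical axes, starting at 0) of Dnmt3a, Psma8, Rapgefl1, Cd244a, Tjp1 and Mmp14 by group; points are libraries and bars the group mean and SD (wild type n = 3, mutant n = 4, Cre-negative n = 2). Dnmt3a was at 118 and 93.5 CPM in the Cre-negative libraries, and Psma8 averaged 12.5 CPM in wild type against 22.2 in mutant libraries.

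The comparison of mutant with wild type asks what the mutant allele does to the transcriptome of these cells. The genes with the lowest p were mostly higher in the mutant. Rapgefl1, a guanine nucleotide exchange factor-like gene, stood at 1.61 ± 0.0856 CPM (SD, n = 3) in wild type and 4.65 ± 0.655 (SD, n = 4) in mutant libraries, a log2 fold change of 1.53 (SE 0.21). Psma8, which encodes a proteasome subunit of the testis, stood at 12.5 ± 0.884 CPM and 22.2 ± 2.54, a log2 fold change of 0.84 (SE 0.13). The meiotic gene Hormad2 averaged 2.51 and 7.28 CPM, Tex14, a gene of germ cell bridges, 1.10 and 4.05 CPM, and the glutathione-cleaving enzyme gene Ggt1 1.25 and 4.76 CPM. Tjp1, which encodes a tight junction protein, went the other way, at 35.9 ± 11.1 CPM (SD, n = 3) in wild type and 15.01 ± 3.95 (SD, n = 4) in the mutant. Wfikkn2, Pyroxd2, Zfp105 and Pcbp4 completed the set, with mutant means 2.11, 2.45, 2.03 and 3.14 times those of wild type in the fitted model. Rapgefl1, Psma8, Tex14, Tjp1, Wfikkn2, Pyroxd2 and Zfp105 also lay on the same side of wild type in Cre-negative libraries, at an unadjusted edgeR p under 0.05. Both comparisons share the wild-type libraries, so such overlap can arise without a shared effect. It does not decide whether these differences are particular to the mutant.

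None of the 10 genes named passed in edgeR fitted to all 9 libraries, which called 0 of 18576 genes between mutant and wild type. In that fit 589 genes had an unadjusted p under 0.05 where chance gives 929, and the adjusted p of these 10 genes ranged from 0.329 to 0.816. Fitted to these 2 groups alone, edgeR also called 0 genes, with 1268 of 17708 at an unadjusted p under 0.05. The unadjusted count thus depended on the fit. DESeq2 called 38 genes (34 higher and 4 lower), limma-voom with sample quality weights 13, and edgeR on these 2 groups with a covariate for Y-linked transcripts, chosen after the data were seen, 26. All of these 10 genes were among those of DESeq2, and Rapgefl1, Psma8, Ggt1, Pyroxd2 and Pcbp4 among the 26; each of the 10 passed in 2 to 7 of 25 alternatives.

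Among the lists fixed in advance, interferon-stimulated genes had the lowest p in this comparison: 41 of 48 measured members had negative log2 fold changes, with a median of -0.16 (camera adjusted p = 5.28e-11). The antiviral genes Mx1 (6.88 ± 2.25 CPM in wild type, n = 3, and 3.62 ± 0.777 in the mutant, n = 4) and Oas2 (11.8 ± 2.99 and 5.98 ± 2.13 CPM) were examples; neither passed the edgeR test. With an estimated correlation the list had an adjusted p = 0.165 in camera. DNA damage sensing and checkpoint genes, the theme in the series title, had 40 of 47 members with negative values and a median of -0.12 (camera adjusted p = 7.85e-05; 0.624 with an estimated correlation). Prkdc, which encodes the DNA-dependent protein kinase, averaged 191 CPM in wild type and 152 in the mutant and did not pass the edgeR test. Histone chaperone and nucleosome remodelling genes (median -0.10), DNA methylation and demethylation genes (-0.06), S phase genes (-0.13) and G2 and M phase genes (-0.09) were also called lower by camera, with adjusted p of 7.91e-04, 0.0177, 0.00133 and 0.0177, and of 0.624, 0.256, 0.777 and 0.850 with an estimated correlation. None of these lists but the interferon-stimulated genes kept its call with each library left out in turn: the medians then ranged from -0.18 to -0.0085 for DNA damage genes, -0.15 to 0.032 for histone chaperones, -0.10 to -0.029 for DNA methylation, -0.30 to 0.048 for S phase and -0.19 to 0.072 for G2 and M phase. The DNA methylation call was lost without mutant_829 (-0.046) and that of G2 and M phase without mutant_824 (-0.056), among others.

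Markers of B cells and neutrophils had higher medians in mutant libraries. Of 24 measured B cell and plasma cell markers, all had positive log2 fold changes (median 0.71, camera adjusted p = 9.20e-11, and 0.467 with an estimated correlation). Relative to the mean of all libraries, this list lay at 0.85 in mutant_829 and 0.69 in mutant_830. It lay at 0.02 in mutant_824 and -0.17 in mutant_827, against -0.59 to -0.12 in wild type, so the mutant libraries were not shifted evenly. Cd79a, part of the B cell receptor, averaged 0.859 CPM in wild type and 1.75 in the mutant. Mature neutrophil markers had a median of 1.16 over 18 members (camera adjusted p = 5.33e-06; 0.544 with an estimated correlation). The granule gene Ngp ranged from 2.46 to 8.67 CPM in wild type and from 4.09 to 37.7 CPM in the mutant. Long-term HSC genes (median 0.16), granulocyte-monocyte progenitor genes (0.13), megakaryocyte genes (0.16) and monocyte, macrophage and dendritic cell markers (0.23) were called higher by camera, with adjusted p of 2.85e-04, 6.89e-05, 9.21e-04 and 8.32e-04, and of 0.624, 0.256, 0.582 and 0.544 with an estimated correlation. Replication-dependent histone genes had a median of 0.32 (camera adjusted p = 1.93e-05; 0.624 with an estimated correlation), which ranged from 0.022 to 0.46 over the left-out libraries and turned direction in the test in 1 of these fits. Germline genes silenced by DNA methylation had a median of 0.19 over 9 measured members (camera adjusted p = 0.0189; 0.396 with an estimated correlation), and Tex14 passed in edgeR when adjusted over the list alone. The HSC, megakaryocyte, germline and monocyte calls were lost in some fits with 1 library left out, with medians from 0.054 to 0.34, 0.040 to 0.29, 0.18 to 0.59 and 0.21 to 0.42.

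The other lists were not called between mutant and wild type by camera on all 9 libraries. With the covariate for Y-linked transcripts, camera called ribosomal protein genes (adjusted p = 8.38e-04, against 0.0901 without it). p53 target genes had a median log2 fold change of -0.004 over 40 members (camera adjusted p = 0.823), and anthracycline target, transport and reduction genes 0.02 over 26 (0.525). Medians were 0.06 for Meis1 and Hoxa leukaemia-associated genes, 0.10 for erythroid genes (12 of 33 members positive in edgeR), 0.23 for T and NK cell markers, 0.10 for mast cell and basophil markers, 0.05 for stromal and endothelial cell markers, 0.13 for imprinted genes, 0.001 for inflammatory and NF-kappaB response genes, 0.03 for ribosomal protein genes and -0.09 for mitochondrially encoded genes. Lymphoid-primed progenitor genes had a median of -0.03 and a mean of 0.04, and immediate early and heat shock genes a median of 0.08 and a mean of -0.12; camera gave both a downward direction. Within the last list the chaperone genes Hspa1a and Hspa1b, near-identical copies whose reads cannot be fully told apart, passed when adjusted over the list alone, at 0.881 ± 0.370 and 0.921 ± 0.229 CPM in wild type (SD, n = 3) against 0.0582 ± 0.0582 and 0.146 ± 0.0594 in the mutant (SD, n = 4).

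**Figure D2:**
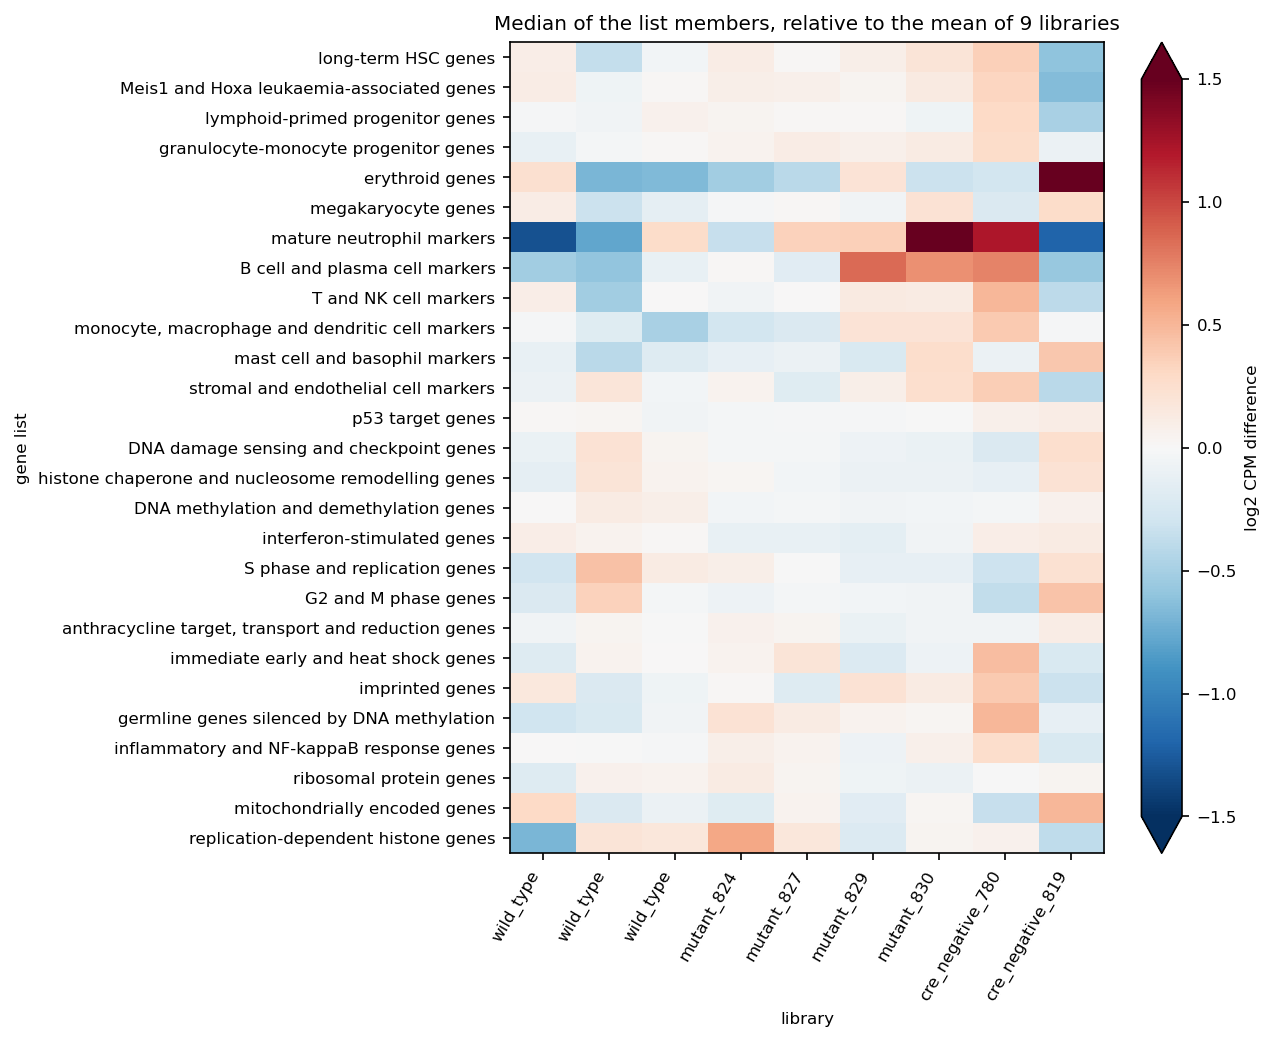
Median log2 CPM of each gene list (rows) in each library (columns), relative to the mean of the 9 libraries; red is higher and blue lower, with the colour scale limited to 1.5. Erythroid genes stood at 1.92 in cre_negative_819 and -0.27 in cre_negative_780, and mature neutrophil markers at 1.84 in mutant_830.

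The comparison of Cre-negative with wild type concerns animals whose genotype is given as Dnmt3a+/-. Psma8 stood at 22.6 ± 0.825 CPM in Cre-negative (SD, n = 2) and 12.5 ± 0.884 in wild-type libraries (SD, n = 3), a log2 fold change of 0.86 (SE 0.15). Psma8 and Rapgefl1 (3.69 and 1.61 CPM) lay on the same side of wild type as in the mutant, and so did Mmp14, a membrane-bound metalloproteinase gene (29.6 and 11.2 CPM). Cd244a, a receptor of the SLAM family, averaged 34.5 CPM in Cre-negative and 56.0 in wild-type libraries. Mrvi1, Aplp2, Unc5cl, Hebp1 and Trib2 were also among the genes with the lowest p, with fitted folds of 2.08, 1.88, 2.20, 2.54 and 3.59. Cd244a, Mrvi1 and Unc5cl also lay on the same side of wild type in the mutant, at an unadjusted edgeR p under 0.05. Their log2 fold changes there were -0.41, 0.43 and 0.73. Trib2 was at 88.3 CPM in cre_negative_819 and 29.1 in cre_negative_780. In the same order, Hebp1 was at 31.8 and 16.8 CPM, Aplp2 at 225 and 147, and Mmp14 at 39.1 and 20.2.

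EdgeR called 0 genes between Cre-negative and wild type, with 972 at an unadjusted p under 0.05 and a smallest adjusted p of 0.421; DESeq2 called 56, each gene named for this comparison so far among them, and limma-voom with sample quality weights 0. The Cre-negative libraries differed from each other, and the count was 650 without cre_negative_780 and 62 without cre_negative_819, each then resting on 1 library whose spread was taken from the other groups.

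Erythroid genes had a median log2 fold change of 1.38 in Cre-negative against wild-type libraries, with 29 of 33 members positive (camera adjusted p = 2.67e-12; 0.348 with an estimated correlation). When adjusted over the list alone, 12 members were higher in edgeR, against 0 over all genes. Car1, a carbonic anhydrase of early red cells, was at 1442 CPM in cre_negative_819 and 108 in cre_negative_780, against 55.1 to 153 in wild type. Without cre_negative_819 the erythroid median became -0.073 and the call was lost. Monocyte, macrophage and dendritic cell markers (median 0.64), B cell and plasma cell markers (0.61), T and NK cell markers (0.50), mast cell and basophil markers (0.39), germline genes (0.37), granulocyte-monocyte progenitor genes (0.24) and ribosomal protein genes (0.06) were also called higher by camera, with adjusted p of 7.83e-08, 0.00312, 0.0448, 0.00738, 0.0170, 0.00738 and 0.0286. S phase genes (-0.15), DNA methylation and demethylation genes (-0.13) and Meis1 and Hoxa genes (-0.18) were called lower, with camera adjusted p of 0.00443, 0.0286 and 0.0146. With an estimated correlation none of the 11 lists passed, the lowest adjusted p being 0.312. In the DNA methylation list, Dnmt3a and Tdg, a DNA glycosylase gene (30.2 ± 2.32 CPM in wild type, n = 3, and 22.1 ± 0.444 in Cre-negative, n = 2), passed when adjusted over the list alone. Without cre_negative_780 the B cell and T cell medians became -0.26 and -0.24, the S phase median 0.059, the granulocyte-monocyte list turned direction in the test at a median of 0.090, and the macrophage, DNA methylation and germline calls were lost (medians 0.39, -0.058 and 0.13). Without cre_negative_819 the Meis1 and Hoxa median became 0.24 and the mast cell call was lost at a median of -0.0029. Leaving out a single wild-type library also ended the T cell, S phase, Meis1 and Hoxa, germline and ribosomal protein calls in some fits, and the ribosomal protein median ranged from -0.033 to 0.086 over the left-out libraries. The ribosomal protein call was lost without either Cre-negative library or any 1 mutant library.

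The comparison of mutant with Cre-negative sets animals with the conditional allele and Mx1-Cre beside animals with the allele and no Cre. Net1 averaged 58.1 ± 2.49 CPM in the mutant (SD, n = 4) and 84.5 ± 2.70 in Cre-negative libraries (SD, n = 2), a log2 fold change of -0.54 (SE 0.10). The interferon-induced genes Iigp1 (49.0 and 108 CPM) and Irf7 (16.2 and 24.7 CPM) also had lower means in the mutant. Wild-type means were 60.2 CPM for Net1, 49.5 for Iigp1 and 19.8 for Irf7. For Net1 and Iigp1 the mutant thus stood near wild type, and the Cre-negative libraries lay above both groups. In cre_negative_780 and cre_negative_819, Iigp1 stood at 81.9 and 134 CPM, and Irf7 at 27.1 and 22.2 CPM. Il1rl1, the interleukin-33 receptor gene, averaged 9.91 CPM in the mutant, and 11.5 and 106 CPM in the Cre-negative libraries. Scin, Gpr174 and Spry4 had mutant means 0.207, 0.436 and 0.284 times those of Cre-negative libraries in the fitted model. Scin stood at 6.46 CPM in cre_negative_780 and 39.7 in cre_negative_819. The immunoglobulin segment Ighv1-80 ranged from 1.25 to 6.17 CPM in the mutant against 0.105 and 0.0916.

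EdgeR called 0 genes between mutant and Cre-negative, with 978 at an unadjusted p under 0.05 and a smallest adjusted p of 0.218; DESeq2 called 27, with Net1, Iigp1, Gpr174, Spry4 and Ighv1-80 among them and Irf7, Il1rl1 and Scin not, and limma-voom with sample quality weights 0. Without cre_negative_780 edgeR called 1835 and without cre_negative_819 it called 9, each then resting on 1 Cre-negative library.

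Interferon-stimulated genes were lower in the mutant, with 40 of 48 members negative and a median of -0.28 (camera adjusted p = 1.33e-11). The list also passed the self-contained test fry (adjusted p = 0.0395), while camera gave an adjusted p = 0.144 with an estimated correlation. In edgeR 7 members were lower when adjusted over the list alone and 0 over all genes; Irf9 averaged 95.3 ± 5.95 CPM in the mutant (SD, n = 4) and 127 ± 3.32 in Cre-negative libraries (SD, n = 2), and Ddx60 48.9 ± 3.90 and 65.7 ± 4.17. Erythroid genes had a median of -1.08 (camera adjusted p = 1.74e-10), which became 0.099 without cre_negative_819 (adjusted p = 0.803 in camera with an estimated correlation). Camera also called long-term HSC genes (0.27), Meis1 and Hoxa genes (0.23), mature neutrophil markers (0.70) and histone genes (0.25) higher, and macrophage markers (-0.23) and immediate early genes (-0.21) lower, with adjusted p of 8.54e-04, 0.00301, 0.0117, 0.00215, 0.0268 and 0.0368. With an estimated correlation none of the 8 lists passed, the lowest adjusted p being 0.144. Without cre_negative_819 the HSC, Meis1 and Hoxa, and neutrophil medians became -0.23, -0.24 and -0.67 and the histone call was lost; without cre_negative_780 the immediate early median became 0.26 and the macrophage call was lost at 0.031. Leaving out a single mutant or wild-type library also ended calls, among them neutrophil markers without mutant_830 (0.28) or mutant_829 (0.82), macrophage markers without mutant_824 (-0.085) or mutant_827 (-0.035), immediate early genes without mutant_829 (-0.036) and histones without mutant_824 (0.20).

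**Figure D3:**
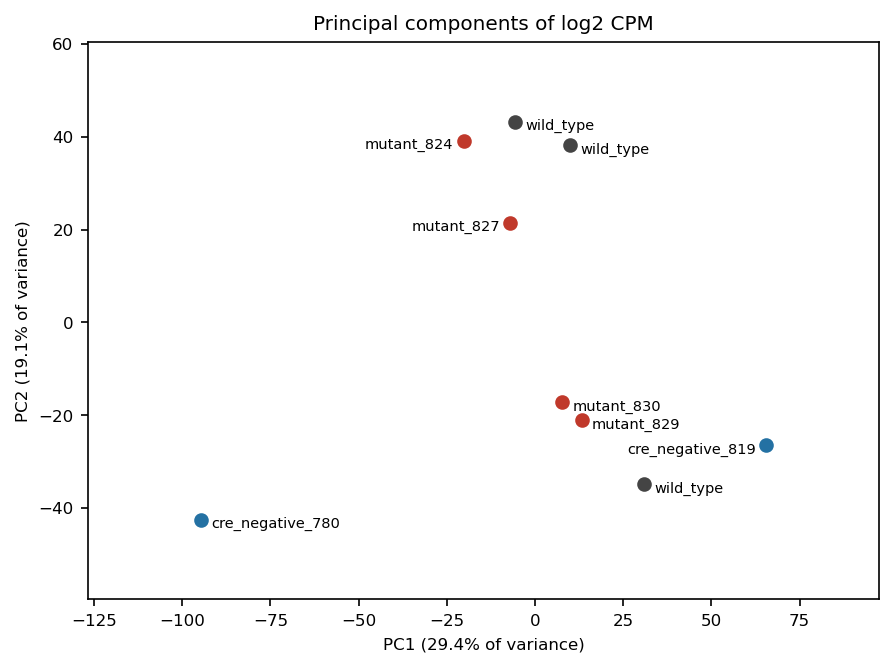
First (horizontal, 29.4% of variance) and second (vertical) principal components of log2 CPM, 1 point per library, coloured by group. cre_negative_780 and cre_negative_819 lay at the ends of the first component, at -94.7 and 65.5.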

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

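Among the 4 mutant libraries, 9 of 271 values tested had 1 library far from the other 3. Chance alone gives this in about 1 group in 20, a share that these 9 values did not exceed. mutant_824 was high for Col1a1 (2.10 CPM, others 0.0530 to 0.266) and low for Rad17 (39.7 CPM, others 43.0 to 43.6). mutant_827 was high for Themis (1.34 CPM, others 0.998 to 1.03) and Hist3h2a (10.5 CPM, others 4.70 to 5.60). mutant_829 was high for Igf2r (84.4 CPM, others 52.2 to 55.9) and Slc25a21 (5.67 CPM, others 2.48 to 2.73). mutant_830 was high for Gatad2b (17.2 CPM, others 14.7 to 14.9), Cavin2 (45.6 CPM, others 37.0 to 38.4) and Ms4a2 (5.78 CPM, others 3.61 to 3.83).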

How the results depend on the processing

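The fits that join the covariate for Y-linked transcripts with another change, the robust fit and the list fits on wild type and mutant alone were chosen after the data were seen; the causes of the differences below were not tested unless given. In the order mutant against wild type, Cre-negative against wild type and mutant against Cre-negative, DESeq2 called 38, 56 and 27 genes where edgeR called 0, and with the covariate 75, 120 and 147. Limma-voom with quality weights called 13 genes in the first comparison, and 113 with the covariate; the fit of these 2 groups with the covariate called 26. With the covariate and cre_negative_780 left out edgeR called 35, 1032 and 2927 genes, and with cre_negative_819 left out 25, 745 and 41. Leaving out each library in turn gave 0 genes in the first comparison, 0 to 650 in the second and 0 to 1835 in the third, above 0 only without cre_negative_780 or cre_negative_819. The remaining alternatives, run on the gene counts with edgeR, and limma-voom in the last 2 comparisons, gave 0.

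Dnmt3a kept its direction and its side of the threshold in both Cre-negative comparisons in each alternative run. Leaving out 1 library gave -0.80 to -0.45 against wild type and 0.48 to 0.83 for mutant against Cre-negative, and -0.034 to 0.10 for mutant against wild type.

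The 14, 11 and 8 lists called by camera became 0, 0 and 0 with an estimated correlation and 0, 0 and 1 with fry; on wild type and mutant alone an estimated correlation also gave 0. With the covariate for Y-linked transcripts, camera also called ribosomal protein genes in the first comparison (adjusted p = 8.38e-04) and immediate early genes in the second (5.99e-05). Leaving out 1 library gave 7 to 15, 9 to 19 and 6 to 17 lists. Medians of lists that turned direction ranged, over the left-out libraries, in the first comparison from -0.30 to 0.048 (S phase), -0.19 to 0.072 (G2 and M phase) and 0.022 to 0.46 (histones); in the second from -0.69 to 0.24 (Meis1 and Hoxa), 0.090 to 0.31 (granulocyte-monocyte), -0.26 to 1.14 (B cell), -0.24 to 0.71 (T and NK), -0.41 to 0.059 (S phase) and -0.033 to 0.086 (ribosomal protein); and in the third from -0.23 to 0.76 (HSC), -0.24 to 0.69 (Meis1 and Hoxa), -2.06 to 0.10 (erythroid), -0.67 to 1.77 (neutrophil) and -0.56 to 0.26 (immediate early). Of 490 list values under alternatives, 361 kept their call, 114 lost it and 15 turned; of 724 named-gene values, 596 stayed past or short of the threshold as before and 128 came to pass it.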

Other observations

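The tests of globin levels, of the germline list, of splits for the count of 0 genes, of splits balanced for Y-linked transcripts and of sex as the whole cause, and the comparison of a covariance with its simulated SD, were chosen after those results were seen. mutant_829 held neither of the transcripts that mark sex: Xist, the RNA that coats the inactive X chromosome, was at 2.07 CPM, against 1567 to 2716 in the 3 libraries that expressed it, and the Y-linked genes summed to 0.0883 CPM against 426 to 475 in the 5 libraries that expressed them. Kdm6a, which is transcribed from both X chromosomes, was at 109 CPM in mutant_829, 188 to 221 in the 3 libraries with Xist and 106 to 115 in those with Y-linked transcripts.

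Over 4 genes known to escape X inactivation (Kdm6a, Kdm5c, Ddx3x and Eif2s3x), the mean log2 CPM of mutant_829 differed by -0.00183 from that of libraries with Y-linked transcripts and by -0.55 from that of libraries with Xist. This argues against 2 X chromosomes with a silent Xist, and is consistent with 1 X chromosome in most of these cells. Whether the animal or its blood cells alone would lack a second sex chromosome, and whether that was an X or a Y, cannot be read from these counts. No DNA was analysed here, so this remains a hypothesis from 1 library.

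The Cre-negative libraries stood apart in opposite ways. cre_negative_819 held 106 CPM of Il1rl1 (7.93 to 16.3 in the other 8 libraries), while its HSC list lay at -0.60 relative to the mean of all libraries. cre_negative_780 had 3.28% of its gene counts on Lars2 and 1.55% on Gm42418, genes overlapping sequence like ribosomal RNA, against at most 0.498% and 0.301% elsewhere; these 2 were chosen after their values were seen. Its HSC list lay at 0.36, and the immediate early gene Egr1 was at 10.3 CPM (0.989 to 5.39 elsewhere).

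In all, 1922 of 13587 genes lay at least 2-fold apart between the Cre-negative libraries, and at most 700 between other libraries of 1 group. Removing ribosomal-like, mitochondrial, histone and small RNA genes before scaling left 1894, which argues against those reads as the cause through scaling. Other pairs of 1 group with and without Y-linked transcripts reached 700, which argues against sex as the whole cause; a part of sex stays open, since pairs across groups reached 1366, for cre_negative_819 itself with mutant_824, and 1922 is not above 1.5 times that, the bound set beforehand. Globin transcripts summed to 6.60 CPM in cre_negative_819, which was not the highest of the 9 libraries and argues against mature red cells, also removed by lysis and lineage depletion. Earlier erythroid progenitors inside the sort, RNA quality and a difference between the animals stay open as possible explanations; none of these was tested, and the design holds no label that separates these 2 libraries.

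A set of 173 genes had an unadjusted p under 0.05 on the same side of wild type in both mutant and Cre-negative libraries, 129 higher and 44 lower, among them Psma8, Rapgefl1, Tex14 and Tjp1. Both comparisons use the same wild-type libraries. In 20 simulations of unchanged groups, 162 to 206 such genes were found, 89 to 137 higher and 59 to 88 lower. The 44 lower genes were fewer than in any simulation. Each gene was drawn independently, however, while real genes move together (estimated correlation 0.88 among G2 and M phase genes, mutant against wild type). The simulated ranges may therefore be too narrow for the 44 lower genes and for the covariance. The covariance of the log2 fold changes was 0.102, against 0.0797 to 0.0979 simulated: the bound set beforehand against shared controls, the highest simulated value, was passed by 0.00458, less than the simulated SD of 0.00478, while Pearson's correlation across genes, which are not independent replicates, was 0.421 and below the simulated 0.438 to 0.505, so the shared controls and a shared effect cannot be told apart. None of the set (0%) lay within 20 Mb of Dnmt3a, where 0.452% of the genes tested lay. With so few genes there, a large share of the set could not fall in this window whatever the cause. The count therefore does not decide on DNA of another strain around the targeted gene. Release of germline genes by lower methylation may contribute and stays open, since the germline list passed in neither comparison with an estimated correlation (lower adjusted p = 0.312 in camera).

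Regrouping the 7 libraries says nothing about the edgeR count of 0 genes between mutant and wild type (DESeq2 38, limma-voom with quality weights 13), since each of the 35 splits gives at least 0; the highest other split, which follows the absence of Y-linked transcripts, gave 5. For the other counts chance could not be excluded over all splits. At an unadjusted p under 0.05, 6 of 35 splits gave at least the real 589 genes, with a highest other of 2337. With the covariate, on these groups alone, 2 of the 34 splits that could be fitted reached the real 26 genes, and the other gave 138. In that split, the smaller part held only libraries with Y-linked transcripts and the larger part 1 such library. With the covariate, its contrast therefore rested on this 1 library. For the lists, 6 of 35 splits gave at least the real 14, with a highest other of 16. Most splits above the real gene count set libraries of 1 class of Y-linked transcripts apart. Among the 18 splits with the real make-up of these classes, 1 of 18, the real one, was highest each time, with 589 genes against 394 at an unadjusted p under 0.05, 26 against 1 with the covariate and 14 lists against 11; 18 splits are too few for a share under 0.05.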
